A study of Mus musculus with 4 samples.

How the data were processed

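DNA methylation was measured by HELP tagging in MC1-ZE7 cells, a mouse embryonic stem cell line (129S6/SvEvTac, passage 31) in which the fluorescent protein Emerald is expressed from the promoter of Zscan4c. Zscan4 genes are expressed in the 2-cell embryo and, at any one time, in a small part of an embryonic stem cell culture. Per the labels' protocols, cells were sorted by Emerald fluorescence, and their genomic DNA was cut either with HpaII, which cuts CCGG only when the central CG is unmethylated, or with MspI, which cuts CCGG whether or not that CG is methylated. A tag of genomic sequence next to each cut was then ligated to adapters, transcribed in vitro, amplified and sequenced. There were 4 libraries: Emerald-high and Emerald-negative cells, each cut with HpaII and with MspI. Each combination had 1 library, so nothing here measures the spread between cultures or sorts.

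The deposited files hold, for each of 1594137 CCGG positions on 21 chromosomes, estimated counts of tags in 2 parts and their sum. The parts added up to the sum at 100% of sites, to within 0.05 tag. Which part is which is not given in the sources used here. Per the file headers, the totals were 5662614 (Emerald-high HpaII), 9372711 (Emerald-high MspI), 9535691 (Emerald-negative HpaII) and 9307616 (Emerald-negative MspI) tags, and the sums over sites equalled them. The counts were not scaled to depth. Between 1.67% and 1.94% of sites per library held fractions of a tag, as when a tag that matches several positions is divided among them. Genome build mm9 is named in the submitters' processing notes. The aligner and the treatment of tags with several matches are not given in the sources used here. No gene annotation of mm9 was used here, so coordinates are given without gene names, and the promoter and gene list comparisons that had been planned were not run.

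Tags were scaled to each library's total over sites. The main measure was the log2 HpaII/MspI ratio in Emerald-high cells minus that in Emerald-negative cells. A positive value means relatively more HpaII cutting, the signature of lower methylation, in Emerald-high cells. Scaling to totals makes every value relative to the library's average, so a change shared by all sites cannot be seen. The log2 difference between the MspI libraries, which do not depend on methylation, is given beside each HpaII value as a gauge of library error. These are separate libraries, so the gauge cannot bound an error particular to the HpaII libraries. Sites were grouped by the number of CCGG positions within 500 bp on either side, the site included: 1 (isolated), 2 to 4, 5 to 9, and 10 or more (dense, the spacing found in CpG islands). The site score was the angle measure used with HELP tagging, 100 × (2/π) × arctan(HpaII/MspI) on scaled tags, for sites with at least 10 MspI tags in each MspI library. A score of 0 means no HpaII tag, and 50 means equal scaled tags. Tags were also summed in 100 kb bins, by chromosome, and over the outermost 2 Mb holding sites at each end of the autosomes and X.

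Sites, and bins with at least 20 MspI tags in each MspI library, were compared with a two-sided Fisher's exact test of HpaII and MspI tags in both cell fractions, the null odds ratio set by the library totals and counts rounded to whole tags. A call needed a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold with a pseudocount of 1 tag. This test compares the libraries, not the conditions. The named bins were the 8 called bins with the largest rise and up to 8 with the largest fall whose MspI libraries differed by at most 0.5 (log2). Confidence intervals are 95%, exact (Clopper-Pearson) for shares and Poisson for log2 ratios. They cover counting error only, and the tags carry no molecular identifiers, so copies of one molecule made in amplification count as separate tags.

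Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9. The exact test matched that of R 4.3.3 to within 1e-04 in 200 of 200 tables. On simulated data for Emerald-high against Emerald-negative cells, the adjusted p recovered 72% of 100 bins changed 2-fold and 99% of 100 changed 4-fold, among 25528 bins. Among 218694 simulated sites it recovered 0% of 100 changed 2-fold and 5% of 100 changed 4-fold. No other bin or site was changed, which makes the adjustment strict, so recovery where many differ was not measured. The comparisons, density classes, minima, naming rule and most alternatives (coverage minima, scaling to dense sites or autosomes, HpaII alone, pseudocounts, bin sizes, an overdispersion factor of 1.38 measured between the MspI libraries, removal of the 0.1% of sites with most MspI tags, thinning) were fixed before the data were examined. The strata by baseline score, their alternatives, the alternative restricted to sites with whole tags, and the list of piled-up positions were chosen after seeing the data. A minimum of Emerald-negative MspI tags in the strata was removed after their values had been seen, so that all scripts share 1 rule; with that minimum, low-score minus high-score strata were 1.07, 1.03, 0.92 and 1.26 from isolated to dense sites. Both tests of depth that were tried, on summed tags and on sites without a HpaII tag after thinning, were dropped after their values were seen, because the first cannot change with depth and the other follows from the shift itself. The prediction on site density had named GC content as well, which was not measured here, and was narrowed after its value was seen.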

Results

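HELP tag libraries were compared between mouse embryonic stem cells sorted as Emerald-high, in which the Zscan4c promoter was active, and Emerald-negative cells. The comparison asks whether DNA methylation differs between Zscan4-positive and Zscan4-negative cells. There was 1 HpaII and 1 MspI library per fraction, with 5662614 (Emerald-high HpaII), 9372711 (Emerald-high MspI), 9535691 (Emerald-negative HpaII) and 9307616 (Emerald-negative MspI) tags. HpaII tags were found at 55.7% of CCGG sites in Emerald-high cells and at 53.7% in Emerald-negative cells, although the Emerald-high library was the shallower. MspI tags were found at 69.5% of sites in both fractions. Across all sites, tag counts of the HpaII libraries had a Spearman correlation of 0.81 and those of the MspI libraries 0.87. Sites are not independent replicates, and no difference below has a replicate check.

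HpaII cutting was distributed differently over the genome in the 2 fractions. In Emerald-high cells, more of the HpaII tags came from isolated CCGG sites and fewer from dense, CpG-island-like clusters. Isolated sites held 27.2% of HpaII tags in Emerald-high cells (95% confidence interval 27.199 to 27.272) and 20.9% in Emerald-negative cells (20.861 to 20.913). Dense sites, which are 8.17% of all sites, held 13.2% in Emerald-high cells (13.156 to 13.211) and 18.2% in Emerald-negative cells (18.174 to 18.223). Sites with 2 to 4 CCGG in the window held 39.5% and 36.2% of HpaII tags, and those with 5 to 9 held 20.1% and 24.8%, in Emerald-high and Emerald-negative cells respectively. The MspI libraries moved less, and the other way except at sites with 2 to 4 CCGG (48.3% in Emerald-negative and 49.6% in Emerald-high cells): isolated sites held 38.0% of MspI tags in Emerald-high cells and 40.7% in Emerald-negative cells, and dense sites 3.92% and 3.29%.

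Relative to MspI, HpaII cutting at isolated sites was 1.40-fold higher in Emerald-high cells, a log2 difference of 0.48 (0.480 to 0.487). At sites with 2 to 4 CCGG the log2 difference was 0.09 (0.0868 to 0.0929). At sites with 5 to 9 it was -0.46 (-0.462 to -0.450), and at dense sites -0.72 (-0.728 to -0.712). The HpaII libraries alone gave log2 differences of 0.38, 0.13, -0.30 and -0.47 from isolated to dense sites, and the MspI libraries -0.10, 0.04, 0.16 and 0.26. Each autosome showed the same order. The HpaII/MspI log2 difference at isolated sites was 0.50 ± 0.03 (mean ± SD over 19 autosomes of the same libraries) and above 0 on 19 of 19, and at dense sites it was -0.72 ± 0.03 and below 0 on 19 of 19. All of these values are relative to library totals. When the libraries were instead scaled to their dense sites, each HpaII/MspI log2 difference rose by 0.72, so isolated sites stood at 1.20, sites with 5 to 9 CCGG at 0.26 and dense sites at 0 by construction.

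**Figure D1:**
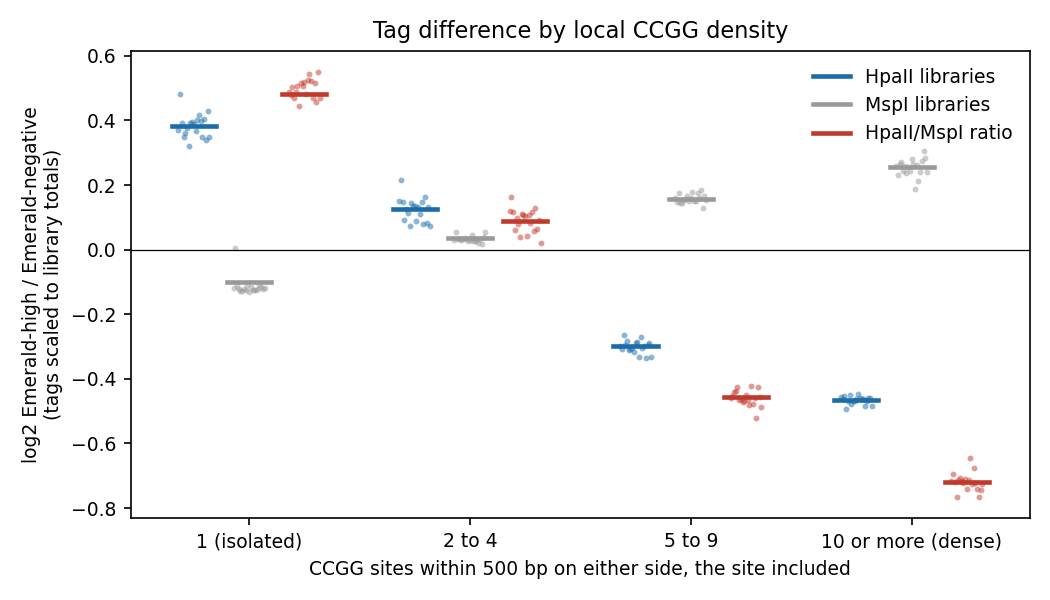
Log2 ratio of scaled tags, Emerald-high over Emerald-negative (vertical axis), for sites grouped by the number of CCGG within 500 bp on either side (horizontal axis). Horizontal bars are the value over all chromosomes and points are the 19 autosomes. The HpaII/MspI value falls from 0.48 at isolated sites to -0.72 at dense sites, while the MspI libraries move from -0.10 to 0.26.

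Single-site scores showed fewer nearly uncut sites in Emerald-high cells. At the 218697 sites with enough MspI tags (13.7% of all sites), the median score was 27.0 (quartiles 10.8 and 50.1) in Emerald-high cells and 14.4 (4.74 and 39.5) in Emerald-negative cells. Scores under 20, sites that HpaII cut rarely, made up 39.6% of sites in Emerald-high cells and 57.6% in Emerald-negative cells. Scaled to dense sites, the medians were 8.50 and 2.64, with 76.8% and 87.2% of sites under 20, so the levels depend on the scaling. No HpaII tag was seen at 9.80% of sites in Emerald-high cells (9.68 to 9.93) and at 15.6% in Emerald-negative cells (15.5 to 15.8). With the Emerald-negative HpaII library thinned to the Emerald-high total, those shares were 10.0% and 23.8%. The score was higher in Emerald-high cells at 65.4% of covered sites and lower at 29.6%.

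By density, the median score of 89721 isolated sites was 26.7 in Emerald-high and 13.1 in Emerald-negative cells, and that of 109343 sites with 2 to 4 CCGG was 23.2 and 12.9. Of 15877 sites with 5 to 9 CCGG the medians were 63.4 and 67.2. At 3756 dense sites they were 79.98 and 84.71, with 49.9% and 73.2% of sites over a score of 80. Among covered sites, dense ones thus had the highest scores in both fractions, and isolated ones and those with 2 to 4 CCGG the lower ones. Only 3756 of 130174 dense sites were covered, against 89721 of 598929 isolated sites, so the scored dense sites may not stand for the rest. Few single sites were called with scaling to library totals. Fisher's exact test on the libraries called 223 of 218697 sites higher and 65 lower in Emerald-high cells. With the Emerald-negative HpaII library thinned to the Emerald-high total, it called 70 higher and 58 lower, and scaled to dense sites 9071 and 3, so the balance of site calls depends on depth and scaling. Of the 223 sites called higher, 142 were isolated and 0 were dense, and of the 65 called lower, 2 were isolated and 22 were dense. At an unadjusted p under 0.05, 30 dense sites were higher and 261 lower.

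**Figure D2:**
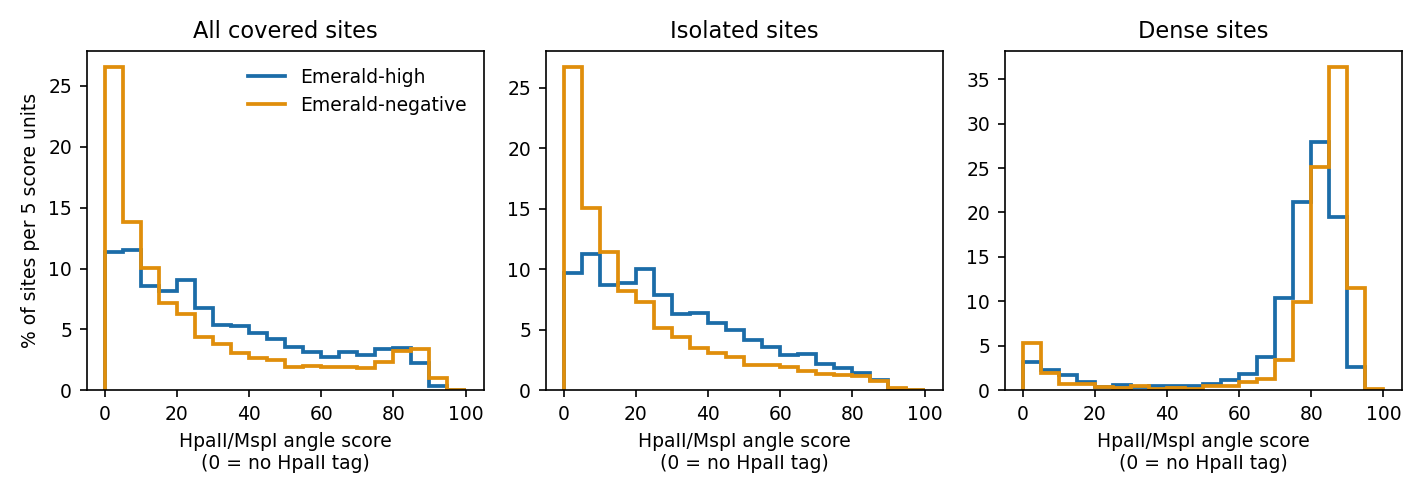
Share of sites (vertical axis, percent per 5 score units) by HpaII/MspI angle score (horizontal axis, 0 means no HpaII tag) in Emerald-high (blue) and Emerald-negative (orange) cells, for all 218697 covered sites, 89721 isolated sites and 3756 dense sites. The Emerald-negative peak at the lowest scores is lower in Emerald-high cells, where 39.6% of all covered sites score under 20 against 57.6%.

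The difference between the fractions followed how much a site was cut in Emerald-negative cells, in every density class. For this comparison, 326743 sites were sorted by an Emerald-negative score from one part of the tags, and the difference was taken from the other part. This score set Emerald-negative HpaII tags against the MspI tags of both fractions together, at least 10 in that part. Across sites, the 2 parts of a library had Spearman correlations of 0.24 to 0.40. Among isolated sites scoring under 20, HpaII tags were higher in Emerald-high cells by a log2 value of 0.96 (0.942 to 0.972; 79023 sites), and among isolated sites scoring over 80 the value was -0.11 (-0.132 to -0.0853; 3386 sites). The MspI libraries moved by 0.00 and -0.12 in these strata, so HpaII/MspI rose by 0.95 (0.936 to 0.968) in the first. It stood at 0.01 (-0.0380 to 0.0521) in the other, no detectable change relative to library totals. Sites with 2 to 4 CCGG gave 0.82 (0.812 to 0.838) under 20 and -0.20 (-0.216 to -0.192) over 80. Sites with 5 to 9 CCGG gave 0.58 (0.533 to 0.626) and -0.34 (-0.348 to -0.325). Dense sites gave 0.84 (0.594 to 1.08; 371 sites) and -0.43 (-0.448 to -0.417; 6127 sites). In the part that gave the difference, isolated sites under 20 held 76986 (Emerald-high) and 66756 (Emerald-negative) HpaII tags. Dense sites under 20 held 278 and 261. Both strata thus had fewer HpaII tags than sites in either fraction. Relative to MspI, the strata under 20 and over 80 stood at 0.77 and -0.26 (2 to 4), 0.49 and -0.49 (5 to 9), and 0.73 and -0.69 (dense). Low-score minus high-score strata differed by 1.07, 1.03, 0.92 and 1.27 from isolated to dense sites in the HpaII libraries and by 0.12, 0.01, -0.07 and -0.15 in the MspI libraries. Sorting by the Emerald-high score instead gave 1.04, 1.01, 0.86 and 0.59, and dense sites scoring under 20 then stood at 0.20 (HpaII) and 0.10 (HpaII/MspI) instead of 0.84 and 0.73, so the rise of rarely cut dense sites depends on which library sorts them.

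**Figure D3:**
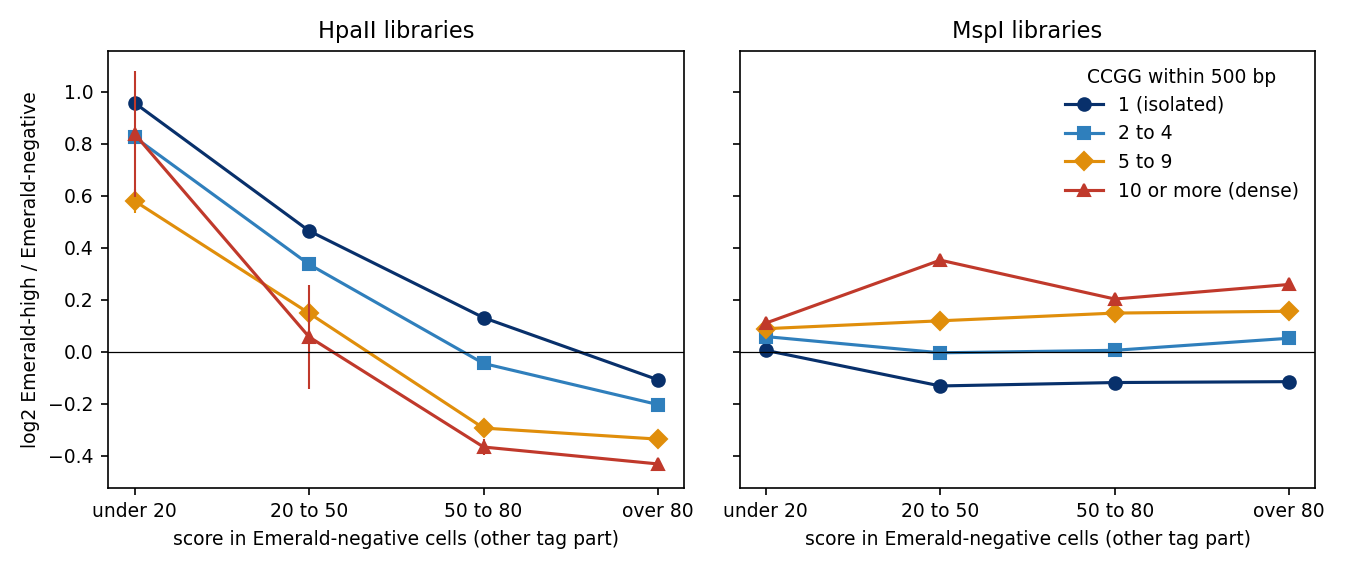
Log2 ratio of scaled tags, Emerald-high over Emerald-negative (vertical axes), against the site's score in Emerald-negative cells taken from the other part of the tags (horizontal axes), for HpaII (left) and MspI (right) libraries. Lines are density classes and vertical lines on the left are 95% Poisson intervals. The score sets Emerald-negative HpaII tags against the MspI tags of both fractions together. HpaII values fall from 0.96 to -0.11 at isolated sites and from 0.84 to -0.43 at dense sites.

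Whole chromosomes differed little from each other. Scaling to library totals fixes their common level, so only the spread between them can be read. Over the 19 autosomes the HpaII/MspI log2 difference averaged 0.01 ± 0.06 (SD over chromosomes), from -0.15 on chromosome 17 to 0.06 on chromosome 13. The chromosome 17 value includes a run of 47 piled-up sites (39979959 to 39985471) with 1.33% of Emerald-high HpaII tags. It moved to -0.05 without the 0.1% of sites with most MspI tags and to -0.34 at well-covered sites. Without the most tagged sites, chromosome 19 (-0.09) was the lowest autosome, followed by 11 (-0.07). Dense sites made up 9.56% of sites on chromosome 11 and 9.18% on chromosomes 4 and 19, the largest shares, and 8.28% on chromosome 17. Chromosome X stood at 0.08 (0.0649 to 0.0939) over all sites. Within density classes it was lower than every autosome at isolated sites, 0.40 (0.376 to 0.421) against 0.44 to 0.55, and higher than every autosome at dense sites, -0.63 (-0.703 to -0.553) against -0.76 to -0.65, an interval that overlaps the autosomes. Over all X sites together the sign turned to -0.08 when only well-covered sites were used. Chromosome Y stood at -0.14 over 1278 sites, but at -0.01 at sites with whole tags, so its value rests on sites with shared tags. Its 484 isolated sites stood at -0.22 (-0.334 to -0.113) and its sites with 2 to 4 CCGG at 0.06 (-0.0828 to 0.210), outside the order of the other chromosomes; whole-tag values by class were not computed.

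**Figure D4:**
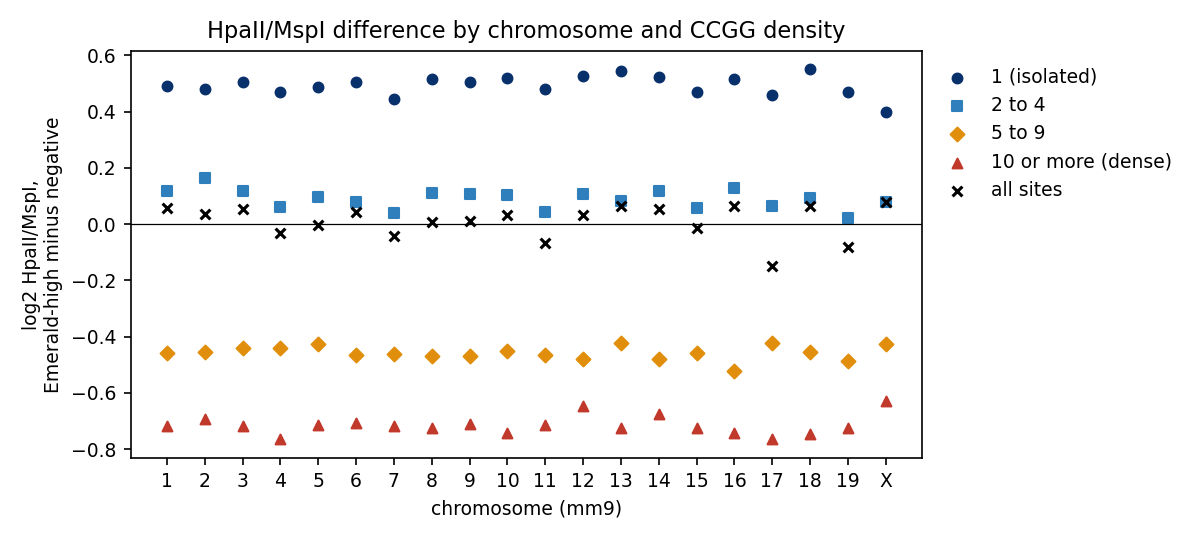
HpaII/MspI log2 difference, Emerald-high minus Emerald-negative (vertical axis), for each autosome and X in mm9 (horizontal axis), over all sites (crosses) and by local CCGG density (symbols). On 19 of 19 autosomes and on X, isolated sites lie above 0 and dense sites below it. Chromosome Y, whose isolated sites stood at -0.22, is not plotted.

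Chromosome ends were compared with the rest because Zscan4 is known for a role at telomeres. Mouse chromosomes have their centromere at the low-coordinate end, so the proximal windows lie on its inner side and do not adjoin a telomere. The outermost 2 Mb had an HpaII/MspI log2 difference of -0.05 (-0.0627 to -0.0318) at proximal ends and -0.10 (-0.114 to -0.0833) at distal ends, against 0.00 (0.000867 to 0.00492) elsewhere. Ends held more dense sites, 8.51% at proximal and 9.65% at distal ends against 8.14% elsewhere. Among isolated sites alone the values were 0.46 (0.430 to 0.488) at proximal ends, 0.46 (0.432 to 0.491) at distal ends and 0.49 (0.481 to 0.489) elsewhere, and among dense sites -0.74, -0.67 and -0.72. For isolated sites taken chromosome by chromosome, proximal ends were above the rest on 12 of 20 chromosomes and distal ends on 8 of 20, with mean differences of 0.00 ± 0.14 and 0.00 ± 0.15 (SD over chromosomes). Sites with 2 to 4 CCGG did differ in the pooled tags, at 0.04 (0.0189 to 0.0671) at proximal ends and -0.02 (-0.0433 to 0.00486) at distal ends against 0.09 (0.0895 to 0.0958) elsewhere. No difference at isolated sites of the ends stood out from the spread between chromosomes, and the other classes were not compared chromosome by chromosome.

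In 100 kb bins, regions without dense clusters were relatively more cut by HpaII in Emerald-high cells. The median HpaII/MspI log2 difference of 25529 bins was 0.26 (quartiles -0.04 and 0.61), with an SD of 0.46 against 0.17 between the MspI libraries. The first SD also holds the counting error of the HpaII tags, so the contrast does not measure variation between bins. Among the 17817 bins with no dense site the median was 0.40 and 84.2% lay above 0. Among 5287 bins with 1 to 19 dense sites the median was -0.02, and among 2418 bins with 20 to 99 it was -0.16, with 30.0% above 0. Fisher's exact test on the libraries, with Benjamini-Hochberg adjustment and at least a 2-fold change, called 1672 bins higher and 5 lower in Emerald-high cells. Of the 1672, 1481 held no dense site. The share of bins called higher ranged from 4.51% on chromosome 7 to 7.71% on chromosome 13 among autosomes and was 6.18% on X. The balance depends on the scaling and the fold limit: by adjusted p alone 5279 bins were higher and 1401 lower, scaled to dense sites 12301 and 0, and in 500 kb bins 9 and 0. Dividing counts by the overdispersion measured between the MspI libraries left 1248 higher and 0 lower calls.

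The bin with the largest rise lay on chromosome 11 at 7400001 to 7500000, where 24 HpaII tags in Emerald-high cells stood against 6 in Emerald-negative cells, beside 142 and 154 MspI tags. Its log2 HpaII/MspI difference was 2.71 (SE 0.68, adjusted p = 0.000101, Fisher's exact test). Chromosome 19 at 39900001 to 40000000 followed with 2.48 (SE 0.51, adjusted p = 9.6e-06, Fisher's exact test), but 9 of its 38 sites held tags shared among positions, and sites with whole tags alone gave 1.84. On chromosome 14 at 72100001 to 72200000 the value was 2.43, from 35 and 11 HpaII tags. On chromosome 9 at 100700001 to 100800000 it was 2.27, from 44 and 16 tags, and on chromosome 18 at 52500001 to 52600000 it was 2.22, from 30 and 10 tags. Chromosome 5 at 18200001 to 18300000 gave 2.18 from 15 and 5 tags. On chromosome X at 161300001 to 161400000 the scaled HpaII ratio was 6.74 (exact interval 1.82 to 37.2) from 12 and 3.25 tags, rounded to whole tags for the ratio. On chromosome X at 73600001 to 73700000 it was 5.89 (1.12 to 58.1) from 7 and 2 tags. A single bin met the naming rule in the other direction: chromosome X at 64800001 to 64900000, with 18 HpaII tags in Emerald-high and 63 in Emerald-negative cells and a log2 difference of -1.17 (SE 0.45, adjusted p = 0.032, Fisher's exact test). The calls of this bin, of the chromosome 5 bin and of the X bin at 73600001 were lost when counts were divided by the overdispersion factor.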

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

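The test of tags mixed into the library was chosen after the result was seen. HpaII and MspI libraries moved in opposite directions between the fractions in 3 density classes, a difference between enzymes that was not tested across replicates, since each group had 1 library. HpaII/MspI log2 differences, Emerald-high minus Emerald-negative, were 0.483 at isolated sites (HpaII 0.38, MspI -0.10), -0.456 at sites with 5 to 9 CCGG (HpaII -0.30, MspI 0.16) and -0.720 at dense sites (HpaII -0.47, MspI 0.26).

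HpaII tags from outside the dense clusters may be more frequent in Emerald-high cells because DNA methylation there is lower, but some other cause in the preparation of 1 library would look alike, so 2 technical explanations were set against this hypothesis. The first was MspI-cut tags mixed in, with the profile of the Emerald-high MspI library. Then 35.1% of an otherwise Emerald-negative library would be needed to bring dense sites to their observed share. On chromosome 2, 3 piled-up sites (98502951 to 98506660) hold 8.63% of Emerald-high MspI tags. With that mix they would hold 4.32 times their observed 0.745% of HpaII tags. Even with no other tag there, they allow at most 8.64%. This bound rests on that run alone, whose HpaII share itself rose from 0.296%, the direction that mixing gives. Other rarely cut runs set looser bounds: Emerald-high HpaII/MspI was 0.407 on chromosome 10 (21862580) and 0.666 to 0.672 on chromosome 8. A mix below the bound is not excluded, and how far it would raise rarely cut sites was not computed. Methylation-independent tags of another profile were not tested. A bias toward site density alone would move isolated sites alike whatever their baseline, but rarely cut isolated sites exceeded highly cut ones by 0.945 (log2) more in the HpaII than in the MspI libraries. GC content, which may differ between rarely and highly cut isolated sites, and the number of molecules each library held before amplification were not measured here and stay open. A density bias joined with a mix below the 8.64% bound stays open too. Lower methylation at sites methylated in Emerald-negative cells predicted that rarely cut dense sites would rise against highly cut ones. They exceeded highly cut dense sites by 1.27. A fall of highly cut sites alone can also give such a gap, and mixed-in MspI tags raise rarely cut sites most. The gap therefore cannot tell lower methylation from a mix below the bound. Sorted by the Emerald-high score the gap was 0.59. Rarely cut dense sites themselves then rose by 0.20 (HpaII) and 0.10 (HpaII/MspI) instead of 0.84 and 0.73. Relative to library totals, most of that gap is thus the fall of highly cut ones. Another scaling moves both strata alike, which keeps the gap but not this split, so the size of the rise is not settled. Differences in HpaII digestion or in the sorted cells that act on methylated sites were not tested and stay open, and only a second pair of libraries would show how the values vary between sorts.

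Most chromosomes were also on opposite sides of 0 in the 2 enzymes, again untested. Their HpaII/MspI log2 differences were 0.0564 (chromosome 1), 0.0551 (3), 0.0433 (6), 0.00835 (8), 0.00950 (9), 0.0314 (10), -0.0673 (11), 0.0327 (12), 0.0641 (13), 0.0543 (14), 0.0626 (16), -0.148 (17), 0.0629 (18), -0.0817 (19) and -0.135 (Y). The same held for proximal ends at -0.0473 and distal ends at -0.0985. Library totals set the 0, and most density classes shifted in opposite directions in the 2 enzymes. Opposite signs by chromosome or end can follow from this by arithmetic and are no separate result. Some values also lay close to 0 in both enzymes, as on chromosome 8 at 0.0046 (HpaII) and -0.0038 (MspI).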

How the results depend on the processing

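Each HpaII/MspI log2 value below is Emerald-high minus Emerald-negative, and the causes of the changes were not tested unless stated. No alternative changed the order of the density classes. Isolated minus dense was 1.20 as reported, 1.22 without the 0.1% of sites with most MspI tags (1594 sites), 1.03 at sites with at least 10 MspI tags in each MspI library, 0.848 with HpaII alone and 1.23 at sites with whole tags. From isolated to dense, the classes were 0.490, 0.0764, -0.467 and -0.728 without the most tagged sites, 0.364, 0.0461, -0.450 and -0.663 at well-covered sites, 0.383, 0.126, -0.299 and -0.465 with HpaII alone, and 0.503, 0.0837 and -0.730 (isolated, 2 to 4, dense) at sites with whole tags. Scaling to dense sites adds 0.72 to each value by construction. It gave 1.204, 0.810, 0.265 and 0 from isolated to dense, and turned the sign of chromosomes 4 (0.687), 5 (0.716), 7 (0.679), 11 (0.653), 15 (0.707), 17 (0.572), 19 (0.639) and Y (0.585). Chromosome values near 0 turned elsewhere too: 2 (-0.00608) and 8 (-0.0163) without the most tagged sites, 8 (-0.00439) at sites with whole tags, and 4 (0.0166), 5 (0.0322), 15 (0.0224) and X (-0.0800) at well-covered sites. Chromosome 17, -0.148 as reported, was -0.0474 without the most tagged sites and -0.344 at well-covered sites, and Y, -0.135 as reported, was -0.0432 and -0.397 there and -0.00539 at sites with whole tags. Ends minus rest was -0.0277 (proximal) and -0.0725 (distal) for the outermost 5 Mb, and -0.0792 at proximal ends at well-covered sites. The difference in median score, 12.6 as reported, was 11.5 with at least 5 MspI tags, 12.1 with at least 20, 12.3 after thinning and 5.86 scaled to dense sites. The difference in the share of scores under 20, -18.0 percentage points as reported, was -15.0, -20.6 and, scaled to dense sites, -10.4. That of scores over 80, -1.53 as reported, was -2.64, -0.974 and, scaled to dense sites, 0.0064. That of sites without a HpaII tag, -5.84 as reported, was -5.15, -4.82 and, thinned, -13.9. Sites called higher, 223 as reported, were 142 with at least 5 tags, 381 with at least 20, 70 after thinning (with 58 lower) and 9071 scaled to dense sites, where 3 were called lower. Bins called higher and lower, 1672 and 5 as reported, were 12301 and 0 scaled to dense sites, 5279 and 1401 by adjusted p alone, 5052 and 189 in 20 kb bins, and 9 and 0 in 500 kb bins. At an overdispersion factor of 1.38 the lower calls were 0, and with at least 50 MspI tags 1. Named bins lost their call 5 times. The X bin at 64800001 did so scaled to dense sites, at the overdispersion factor and with a pseudocount of 5. At the overdispersion factor the X bin at 73600001 and the chromosome 5 bin lost theirs too. These last 2 bins had too few tags to be tested at 50 MspI tags. Adjusted p alone cannot end a call. Low-score minus high-score strata, chosen after seeing the data, were 0.883 (2 to 4) and 0.735 (5 to 9) with the tag parts exchanged, 1.154 (isolated) and 1.142 (2 to 4) with at least 20 MspI tags, and 1.007 (2 to 4), 0.864 (5 to 9) and 0.591 (dense) sorted by the Emerald-high library. Single sites were recovered least: the simulated 4-fold changes, planted in few features, were found at 5% of sites and in 99% of bins. A share of HpaII tags per density class has no value under HpaII alone or scaled to dense sites. Promoter and gene list alternatives were not run, since no annotation of mm9 was used. No paired analysis was possible because each group had 1 library.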

Other observations

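The list of piled-up positions was chosen after the tag counts were seen; the bound of the test of regional differences was written before its result, but the allowance for error around that bound was added after the result was seen. Positions with over 1000 tags in any library (tags within 10 kb of each other joined) formed 41 runs, which were not compared with any repeat annotation. The run on chromosome 2 at 98502951 to 98506660, an interval known from background knowledge to collect major satellite sequence of pericentromeric heterochromatin, held 8.63% and 8.15% of MspI tags in Emerald-high and Emerald-negative cells but 0.745% and 0.296% of HpaII tags. Its HpaII/MspI ratio was 0.0864 in Emerald-high and 0.0363 in Emerald-negative cells, a 2.38-fold difference (log2 1.25, counting interval 1.23 to 1.27). At chromosome 10, position 21862580, the log2 difference was 1.87 (1.67 to 2.08). Single sites on chromosome 8 at 19761783, 19922611 and 73649652 gave 0.89, 0.89 and 0.92, and their near-equal tag counts point to shared tags, not to independent sites. These were the 5 runs with less scaled HpaII than MspI in Emerald-negative cells. Of the 36 others, 28 were lower and 8 higher in Emerald-high cells, with a median of -0.51 and a range from -1.21 to 0.36. Neither group supports a direction by its count, since several runs in each have equal or near-equal counts in all 4 libraries, and the ratio that splits the groups also enters the difference. Among the 36, the run of 47 sites on chromosome 17 at 39979959 to 39985471, known from background knowledge to match the ribosomal RNA gene repeat, stood at -0.62 (-0.641 to -0.592), close to the -0.69 of highly cut dense sites, and chromosome 2 at 22444105 to 22444768 stood at 0.04 (-0.0135 to 0.0895).

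Whether the difference has a regional part beyond site density and baseline cutting was tested on 100 kb bins, as a hypothesis. Only bins with at least 100 HpaII and at least 100 MspI tags in the part used, both fractions together, were kept. The result therefore does not cover bins with fewer tags. HpaII differences of adjacent bins (10834 pairs, one part of the tags) had a correlation of 0.16, and 0.10 after subtracting what density class and baseline score predict, against 0.01 for the MspI libraries treated alike. The excess of 0.0921 met the bound written in advance (no more than 0.1), which without an allowance for error would have counted for density and baseline alone. With the allowance of 0.027, or with a jackknife over 21 chromosomes (95% interval 0.0569 to 0.127), it lies on neither side of that bound, so density and baseline alone cannot be told apart from an added regional part. The baseline score was defined only for the 326743 sites of the strata. At other sites only density class could be subtracted, so baseline cutting left there may make up part or all of the excess. Bins are not replicates, and both HpaII libraries enter each pair.

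A pair of relations over the 19 autosomes, not among the planned comparisons, was computed. Chromosomes with a larger share of dense sites had a lower HpaII/MspI log2 difference (Pearson r = -0.56, permutation p = 0.013, adjusted p = 0.013; Spearman rho = -0.54, p = 0.019) and a higher MspI difference (r = 0.60, permutation p = 0.0071, adjusted p = 0.013; rho = 0.62, p = 0.0062), with adjustment over 2 relations. Without the 2 autosomes farthest from the median share, r was -0.37 (permutation p = 0.15) and 0.46 (p = 0.068), weaker and of the same sign. A chromosome's value mixes its density classes, so the density result gives relations of these signs by arithmetic, and they are no separate support for it. How much of either relation it accounts for was not computed. The autosomes come from the same libraries and are not independent replicates.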
